A study of Mus musculus with 8 samples.

How the data were processed

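Spinal cord RNA from 8 mice was sequenced as 1 library per mouse, 4 labelled heterozygous and 4 labelled homozygous. Reads were trimmed with cutadapt, aligned with STAR to mm10 and counted per gene with RSEM, with quality measures from Picard, per the submitters' processing notes. Their versions and the gene annotation are not given in the sources used here. The authors deposited, for each library, RSEM expected counts, TPM and FPKM per gene, per the file headers, with other columns such as the effective gene length. The deposited series tables of expected counts and FPKM held the same values as the library tables (largest difference 0). The authors' deposited table of their comparison gives log2 fold changes, log2-CPM, p-values and false discovery rates, per the file headers. The authors deposited it as an edgeR result, whose settings and filter are not given in the sources used here. The deposited sequencing report gives other values per library, such as reads, percent mapped, percent ribosomal bases and RNA integrity number; 99.4% to 99.6% of reads were on the expected strand. The deposited demultiplexing summary was not used here.

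Expected counts were rounded to whole numbers. RSEM divides reads shared by similar genes, so genes with close copies, such as Fth1, the hemoglobin genes and the mitochondrial genes with nuclear copies, are less certain. Library totals of 26321522 to 37879426 expected counts leave genes under 1 CPM with few counts. Groups come from the genotype label, and each title carries its own animal number. The replicate numbers follow the order of deposition and were not used as pairs. The labels give no pairing, litter or cohort, so whether animals of the groups were matched is not known. Of 47643 gene identifiers 47224 matched GENCODE release M21, used for positions (GRCm38, the assembly also called mm10).

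The test, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Homozygous was compared with heterozygous by edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. SE is that of the log2 fold change. CPM are TMM-scaled. Of 41 gene lists, 39 with at least 5 tested genes were tested by camera (limma 3.58.1) at a preset correlation of 0.01, and beside it with an estimated correlation and by fry; the lists of B and plasma cells and of adipocytes had too few tested genes. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the figures.

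Named genes were Arf1 to Arf6; up to 10 higher and 10 lower genes with the smallest p past the threshold whose groups did not overlap, or the 5 with the smallest p in each direction where none passed; the 10 largest changes past the threshold with a mean log2-CPM above 0; and up to 4 genes past the threshold from each called list and 2 from other lists. Predicted genes, Xist and Y-linked genes were left out, and any list member could be given as a value that did not pass. The rule was applied again without the library labelled homozygous replicate 1, which was decided after its Arf1 level was seen.

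Alternatives were median-of-ratios size factors, no filter, at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a fit that was not robust, limma on log2(TPM + 1), Xist as a covariate, an adjusted p of 0.1, an absolute log2 fold change of at least 1, and each library left out. The Xist covariate was the log2-CPM of Xist in each library, not a label of sex. The 6 libraries of the authors' gene tables, and every alternative within the 7 libraries, were added after seeing the data. The procedure was tested on simulated counts. With 8 libraries (16386 genes) it recovered 58.2%, 85.1% and 100.0% of genes changed 1.5-, 2- and 4-fold, and 4.71% of its calls were unchanged genes. With 7 libraries (16398 genes) it recovered 62.7%, 82.1% and 98.5%, and 7.43% of its calls were unchanged genes. The simulated counts were drawn independently for each gene. Changed genes had a mean above 1 CPM and the same change in every homozygous library. No simulated library went against its label, so these shares need not hold for the real libraries.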

Results

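RNA was sequenced from the spinal cord of 8 C57BL/6 mice, in which Arf1 was to be deleted by tamoxifen given at 100 mg/kg. Arf1 encodes a small GTPase that recruits coat proteins, among them the COPI coat, to Golgi membranes. The submitters' design note names the role of Arf1 in neurons as the subject, and the series title names peroxidated lipids, loss of myelin and the NLRP3 inflammasome of microglia. The labels give 4 mice as heterozygous and 4 as homozygous, aged 2 to 10 months, with neither age nor sex for single animals. The libraries held 29857210 to 37803594 expected counts in the heterozygous and 26321522 to 37879426 in the homozygous group.

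Arf1, the gene to be deleted, was low in 3 of the 4 libraries labelled homozygous. Its level was 314 ± 16.6 CPM in the heterozygous libraries (SD, n = 4) and 22.4, 22.7 and 39.8 CPM in homozygous replicates 2, 3 and 4. In the library labelled homozygous replicate 1 it was 308 CPM, within the heterozygous range of 297 to 333 CPM, so the Arf1 level of this library goes against its label. Over all 8 libraries the log2 fold change was -1.67 (SE 0.95) and did not pass edgeR's quasi-likelihood test (adjusted p = 0.42). Without the library labelled homozygous replicate 1 it was -3.46 (SE 0.21, edgeR adjusted p = 0.000796). That library was left out for its Arf1 level, so this p is not an independent test of Arf1. Arf1 lies on the minus strand of chromosome 11, from 59211412 to 59228270 (GRCm38). Its paralogs Arf2 to Arf6 did not pass edgeR's test in either fit. In the fit that left out the library labelled homozygous replicate 1 their log2 fold changes lay between -0.06 for Arf2 and 0.17 for Arf5, and the signs of Arf3, Arf4 and Arf5 turned on the log2 TPM scale and that of Arf6 with another filter or with 1 library left out. On that scale Arf2 passed (limma adjusted p = 0.047, the lowest of its alternatives, which reached 0.883).

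Mrpl55 and 2310033P09Rik, beside Arf1, were low in the same 3 libraries. Mrpl55, which encodes a mitochondrial ribosomal protein and spans 59202486 to 59206134 on the plus strand, fell from 13.1 ± 1.03 to 3.27 ± 0.368 CPM (SD, n = 4 and 3) without the library labelled homozygous replicate 1 (log2 fold change -1.99, SE 0.12, edgeR adjusted p = 0.000385). Between Mrpl55 and Arf1 lies 2310033P09Rik, from 59208321 to 59210738, which fell too (log2 fold change -1.47, SE 0.13, edgeR adjusted p = 0.00208). It was chosen after its values were seen. In the library labelled homozygous replicate 1 these 2 genes stood at 14.5 and 7.71 CPM, at the heterozygous level. They followed Arf1 there, so leaving out that library for its Arf1 level also favoured their p. Guk1, Iba57, 2610507I01Rik, Wnt9a and Snap47, also within 200 kb of Arf1, did not pass.

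**Figure D1:**
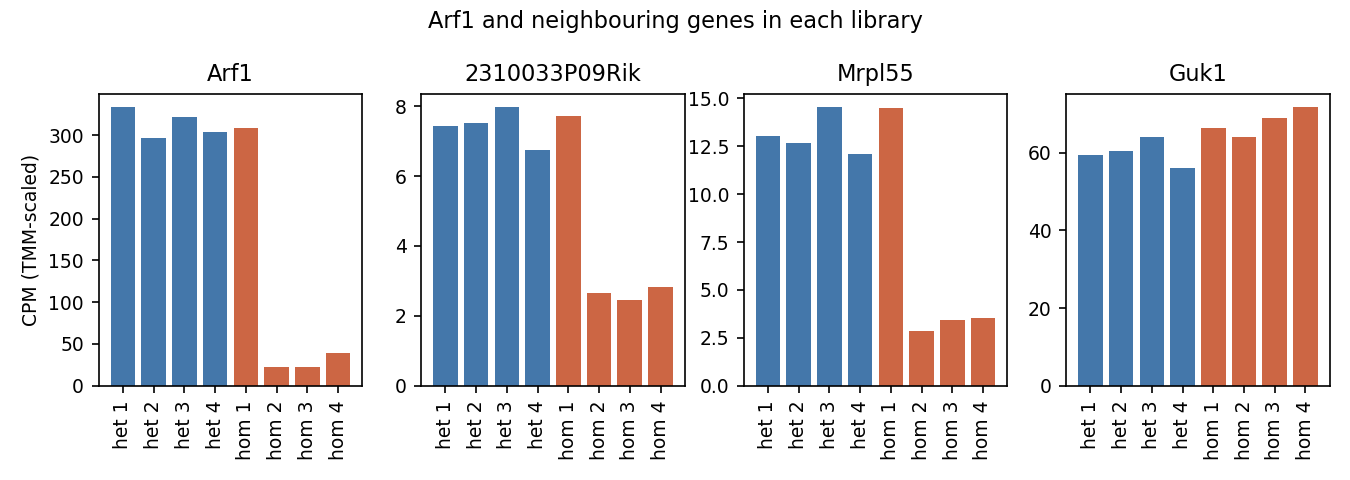
Bars give the TMM-scaled CPM of Arf1, 2310033P09Rik, Mrpl55 and Guk1 in each library (het, labelled heterozygous; hom, labelled homozygous; 1 bar per library, no error). Arf1 stood at 308 CPM in hom 1 and at 22.4 to 39.8 CPM in hom 2 to hom 4, while Guk1 was at 59.9 ± 3.30 CPM in the heterozygous and 67.8 ± 3.25 CPM in the homozygous-labelled libraries (SD, n = 4 and 4).

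Between the 4 libraries labelled homozygous and the 4 heterozygous ones, no gene passed. edgeR called 0 genes higher and 0 lower of 16511 tested, with 1299 higher and 1470 lower at an unadjusted p under 0.05. limma-voom called 0 and 0, and DESeq2 270 and 409. Leaving out the library labelled homozygous replicate 1, edgeR called 91 and 111, and without heterozygous replicate 1 it called 4 and 36. The genes with the smallest p, none of which passed, included Dhh, the hedgehog ligand made by Schwann cells, at 1.44 ± 0.626 and 0.107 ± 0.0669 CPM (SD, n = 4 and 4, edgeR adjusted p = 0.0734). Smtn, a smooth muscle cytoskeletal gene, was at 9.06 ± 1.90 and 3.91 ± 0.640 CPM, Igdcc4 at 48.7 ± 2.12 and 33.1 ± 3.39 CPM, Banp at 26.6 ± 2.18 and 17.3 ± 1.47 CPM and Sh3pxd2b at 24.8 ± 2.03 and 16.2 ± 1.51 CPM. With higher means, Zfos1 was at 15.6 ± 0.900 and 25.1 ± 1.91 CPM (edgeR adjusted p = 0.0574), the secreted phospholipase Pla2g3 at 3.53 ± 0.313 and 8.52 ± 2.40 CPM, Mir124-2hg, a host transcript of a neuronal microRNA, at 23.5 ± 0.969 and 31.6 ± 2.05 CPM, RP23-144N15.10 at 0.234 ± 0.0767 and 1.01 ± 0.280 CPM and Sh2d1a at 8.88 ± 0.275 and 12.3 ± 0.577 CPM.

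The mean of a list of Schwann cell genes, of the myelinating cells of nerve roots, was lower in each of the 4 libraries labelled homozygous than in any heterozygous one. Its genes did not all go that way, as 2 of 10 had a positive log2 fold change. Prx, which encodes periaxin, was at 2.15, 3.88, 8.53 and 1.33 CPM in replicates 1 to 4 labelled homozygous and at 34.4 ± 20.6 CPM in the heterozygous libraries, and Pmp22 was at 121 ± 53.7 and 37.4 ± 8.46 CPM (SD, n = 4 and 4). None of the 10 genes passed over all genes tested, while adjusted over the list alone 8 were lower and 2 higher. The list was lower, with a median log2 fold change of -1.23 (camera adjusted p = 4.31e-08; adjusted p = 0.397 with an estimated correlation). With the library labelled homozygous replicate 1 left out its median was -1.12 (camera adjusted p = 3.62e-05; adjusted p = 0.37 with an estimated correlation). Of 39 list means, those of cholesterol synthesis and endothelial genes also lay below every heterozygous library in all 4 libraries labelled homozygous, and that of lipid droplet genes above (exact permutation p = 0.0286 for each of the 4, not adjusted). The lipid droplet genes did not rise as a group. With 8 libraries 7 of 14 had a positive log2 fold change, with a median of -0.003 (camera adjusted p = 0.834). The list of meningeal fibroblast genes was lower too, at a median of -0.55 over 12 genes, 4 of them lower adjusted over the list alone and 0 over all genes (camera adjusted p = 7.32e-05; adjusted p = 0.575 with an estimated correlation). The fibroblast call was lost with limma on log2 TPM (adjusted p = 0.0592), against 4.66e-08 at the lowest of its alternatives. In the fit that left out the library labelled homozygous replicate 1 their median was -0.41 (camera adjusted p = 0.0108; adjusted p = 0.651 with an estimated correlation). The fibroblast call was lost without heterozygous replicate 3 (adjusted p = 0.0802), heterozygous replicate 4 (0.0934) or homozygous replicate 2 (0.119) and with limma-voom (0.0527) or limma on log2 TPM (0.414), against 9.22e-05 at the lowest of its alternatives. The fibrillar collagen gene Col3a1 fell from 8.45 ± 3.47 to 1.67 ± 0.712 CPM without the library labelled homozygous replicate 1 (log2 fold change -2.33, SE 0.43, edgeR adjusted p = 0.0498) and was at 2.33 CPM in that library. With 1 more library left out it lost its call in 6 of the 7 fits. Myelin genes of oligodendrocytes had a median of -0.27 with 0 of 16 past edgeR's test, over all genes and adjusted over the list alone (camera adjusted p = 0.0343; adjusted p = 0.788 with an estimated correlation); the call was lost without the library labelled homozygous replicate 1 (adjusted p = 0.0544) and without heterozygous replicate 3 (adjusted p = 0.117), heterozygous replicate 4 (0.144), homozygous replicate 2 (0.246) or homozygous replicate 3 (0.175) and with limma-voom (0.0501) or limma on log2 TPM (0.252), against 4.8e-07 at the lowest of its alternatives. Its median was -0.16 without homozygous replicate 2 and -0.46 without homozygous replicate 4.

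The comparison was repeated without the library labelled homozygous replicate 1, with 4 heterozygous and 3 homozygous libraries, and single genes then passed. edgeR called 91 genes higher and 111 lower of 16560. Unscaled counts gave 60 higher and 150 lower, and log2 TPM, where the median of all genes moved to -0.17, gave 95 and 2095. The calls rest on few libraries: 3 higher and 3 lower genes were called without homozygous replicate 3, 14 higher and 8 lower without homozygous replicate 2, and 139 higher and 263 lower without homozygous replicate 4. Without heterozygous replicates 2, 3 and 4 in turn there were 27 higher and 31 lower, 32 higher and 19 lower, and 16 higher and 17 lower. Of the 48 genes named by rule and called here, 43 lost the call without homozygous replicate 3, 29 without homozygous replicate 2, and 25, 22 and 27 without heterozygous replicates 2, 3 and 4; 7 lost it without heterozygous replicate 1 and 5 without homozygous replicate 4. With Xist as a covariate 33 higher and 30 lower genes were called, and 19 of the 48 lost the call. That covariate is not sex alone, since Xist also varied among libraries with Y-linked transcripts, from 0 CPM in heterozygous replicate 3 to 44.4 CPM in heterozygous replicate 1. Of the 48 genes, 7 lost the call with limma-voom and 6 with a fit that was not robust. Arf1, Mrpl55, Mt1, Pla2g3 and Phyhd1 kept it with any 1 library left out. For Arf1 and its neighbour Mrpl55 this is no independent support, since the 7 libraries were chosen with the Arf1 level in view. The gene values that follow are from these 7 libraries (mean ± SD, n = 4 and 3).

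The 2 microglial lists went opposite ways. Of 20 genes of disease-associated microglia 4 rose, and 11 adjusted over the list alone. Clec7a, a pattern recognition receptor, rose from 0.492 ± 0.118 to 3.75 ± 1.79 CPM (log2 fold change 2.92, SE 0.35, edgeR adjusted p = 0.0122), and Cst7, which encodes cystatin F, rose too (log2 fold change 4.10, SE 0.49, edgeR adjusted p = 0.0122). Itgax, which encodes the integrin CD11c, rose from 0.334 ± 0.189 to 1.90 ± 0.773 CPM, and Cd68, a lysosomal protein of phagocytes, from 5.77 ± 0.467 to 10.2 ± 2.33 CPM. The list was higher (camera adjusted p = 1.64e-11; adjusted p = 0.37 with an estimated correlation). Its median of 0.49 was 0.29 without homozygous replicate 4, the library with the highest list mean and with an RNA integrity number of 8, against 9 in the other 7. Among 14 genes of resting microglia 1 fell, and 8 adjusted over the list alone (camera adjusted p = 8.21e-05; adjusted p = 0.526 with an estimated correlation). Tmem119, a marker of resident microglia, fell from 21.9 ± 1.65 to 14.7 ± 2.06 CPM (edgeR adjusted p = 0.0462), while the purinergic receptor gene P2ry12 was at 29.1 ± 3.94 and 17.7 ± 3.97 CPM and did not pass. With 1 library left out, the call was lost by Itgax in 7, Tmem119 in 6, Cd68 in 5 and Clec7a and Cst7 in 1 of the 7 fits. In the library labelled homozygous replicate 1 Clec7a was at 0.656 and Tmem119 at 22.0 CPM.

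Among genes of the first complement component, C1qa rose from 44.2 ± 3.92 to 78.0 ± 13.9 CPM and C1qb from 45.7 ± 4.61 to 68.7 ± 11.4 CPM, 2 of 15 complement genes, or 5 adjusted over the list alone (camera adjusted p = 0.000283; adjusted p = 0.526 with an estimated correlation). Of 16 lysosomal genes, 2 rose, Cd68 and Grn, which encodes progranulin and rose from 47.5 ± 4.08 to 71.8 ± 12.2 CPM; adjusted over the list alone 7 rose and 1 fell. The lysosomal list was higher (camera adjusted p = 0.00754; adjusted p = 0.651 with an estimated correlation). The lysosomal call was lost without homozygous replicate 4 (adjusted p = 0.389) and with limma on log2 TPM (0.101), against 4.27e-05 at the lowest of its alternatives. On log2 TPM its median turned to -0.066. Of 6 chemokine and cytokine genes, Ccl3 rose from 0.0820 ± 0.0557 to 1.23 ± 0.571 CPM and Il33, an alarmin of glia, fell from 68.6 ± 5.18 to 36.1 ± 8.45 CPM; adjusted over the list alone 2 rose and 2 fell. That list was not called (camera adjusted p = 0.809). The call was lost by C1qb and Grn in 6, Il33 in 4 and C1qa and Ccl3 in 2 of the 7 fits with 1 library left out. Genes of monocytes and neutrophils, 7 tested with 0 past edgeR's test and 1 adjusted over the list alone, were higher as a list (camera adjusted p = 0.011; adjusted p = 0.651 with an estimated correlation). The monocyte and neutrophil call was lost without homozygous replicate 4 (adjusted p = 0.912) and with Xist as a covariate (0.0713), against 8.87e-07 at the lowest of its alternatives.

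Inflammasome and interleukin-1 genes did not pass. Nlrp3, the sensor named in the series title, was at 0.674 ± 0.148 and 0.665 ± 0.229 CPM (log2 fold change -0.01, SE 0.32), a level at which only a large change was detectable. Casp1 was at 1.87 ± 0.512 and 1.97 ± 0.0801 CPM, Il1b at 0.238 ± 0.167 and 0.305 ± 0.0900 CPM and Il18 at 7.65 ± 1.11 and 9.14 ± 0.822 CPM. These are RNA levels of the spinal cord, and inflammasome protein or activity was not measured. The list of 12 genes was not called (camera adjusted p = 0.767), nor were 22 interferon response genes (0.286) and 14 genes of MHC class I (0.45). Genes of MHC class II, which presents antigen, had a median log2 fold change of -1.10 with none of 7 past the test and 4 lower adjusted over the list alone (camera adjusted p = 0.00571; adjusted p = 0.526 with an estimated correlation). That call was lost with limma on log2 TPM (adjusted p = 0.179), against 0.000204 at the lowest of its alternatives. T cell genes were not called by camera (0.407), while fry, which tests whether genes move one way on balance, gave an adjusted p of 0.00983. Of 5 T cell genes 0 passed, over all genes and adjusted over the list alone. The T cell list mean was 0.718 log2-CPM in homozygous replicate 2, and 0.269 and 0.306 in homozygous replicates 3 and 4. In the heterozygous libraries it ranged from -0.0167 to 0.292. All 5 genes had a positive log2 fold change, with a median of 0.08 and a mean of 0.50. Cd4, a gene of this list, was well above the heterozygous mean in homozygous replicate 2 and below it in homozygous replicates 3 and 4. Lists of border macrophages (0.767) and proliferation (0.896) were not called.

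Among genes of reactive astrocytes shared by several injuries, 2 of 13 rose, and 4 adjusted over the list alone. Serpina3n, an acute-phase protease inhibitor, rose from 26.6 ± 2.31 to 77.8 ± 28.5 CPM (log2 fold change 1.56, SE 0.21, edgeR adjusted p = 0.0278), and Timp1, an inhibitor of metalloproteinases, rose from 0.469 ± 0.216 to 2.77 ± 1.78 CPM. Gfap, the astrocyte intermediate filament gene, was at 373 ± 44.3 and 834 ± 446 CPM and did not pass. The list was higher (camera adjusted p = 7.17e-05; adjusted p = 0.526 with an estimated correlation). Its median of 0.51 was 0.15 without homozygous replicate 4, whose list mean of 3.64 log2-CPM stood against 2.90 and 2.75 in homozygous replicates 2 and 3. The RNA integrity number of homozygous replicate 4 was 8, against 9 in the other 7. With 8 libraries the list was also higher (camera adjusted p = 0.0163; adjusted p = 0.701 with an estimated correlation). That 8-library call was lost without heterozygous replicate 2 (adjusted p = 0.0659) or homozygous replicate 4 (0.247) and with limma-voom (0.0944) or Xist as a covariate (0.0727), against 7.17e-05 at the lowest of its alternatives. With 1 library left out, Timp1 and Serpina3n lost the call in 6 and 5 of the 7 fits. The astrocyte lists A1 (camera adjusted p = 0.22), A2 (0.373) and homeostatic (0.356) were not called. Outside these lists, the metallothionein gene Mt1 rose from 129.9 ± 7.23 to 258 ± 18.9 CPM (edgeR adjusted p = 0.000796) and was at 126 CPM in the library labelled homozygous replicate 1.

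The 3 neurofilament genes, which encode the main filaments of large axons, fell. Nefm fell from 837 ± 91.3 to 448 ± 84.2 CPM (log2 fold change -0.89, SE 0.13, edgeR adjusted p = 0.0223), Nefl from 839.8 ± 61.0 to 576 ± 31.2 CPM and Nefh from 313 ± 57.9 to 163 ± 28.9 CPM. With 1 library left out, the call was lost by Nefh in 6, Nefm in 5 and Nefl in 4 of the 7 fits. No other of the 16 pan-neuronal genes passed, and adjusted over the list alone 4 fell. The list had a median of -0.05 (camera adjusted p = 0.0023; adjusted p = 0.526 with an estimated correlation), which was -0.029 without heterozygous replicate 1, -0.019 without heterozygous replicate 2, -0.093 without heterozygous replicate 4, -0.027 without homozygous replicate 2 and -0.11 without homozygous replicate 3. Motor neuron genes had a median of -0.57 with 0 of 12 past edgeR's test, over all genes and adjusted over the list alone (camera adjusted p = 0.00122; adjusted p = 0.553 with an estimated correlation). The motor neuron call was lost with limma on log2 TPM (adjusted p = 0.162), against 9.86e-09 at the lowest of its alternatives. Hoxc10, a gene of caudal cord segments chosen after its values were seen, was at 3.55 to 15.1 CPM in the heterozygous libraries, 10.4 CPM in the library labelled homozygous replicate 1 and 1.11 to 5.97 CPM in the other 3. The labels used here give no cord segment, so the segments sampled may differ between the groups of this fit. Whether this lowered the neurofilament or motor neuron genes was not tested. Of 11 immediate early genes 2 rose, Btg2 from 13.1 ± 0.572 to 23.4 ± 2.52 CPM and Cyr61 from 4.99 ± 0.465 to 10.4 ± 1.17 CPM, and 7 adjusted over the list alone (camera adjusted p = 2.77e-09; adjusted p = 0.37 with an estimated correlation). Each of these 2 lost the call in 1 of the 7 fits with 1 library left out. The nerve injury list was higher with 0 of 13 genes past edgeR's test and 1 adjusted over the list alone (camera adjusted p = 0.0315; adjusted p = 0.37 with an estimated correlation). The injury call was lost without heterozygous replicate 3 (adjusted p = 0.0888) or homozygous replicate 4 (0.148) and with Xist as a covariate (0.0625), against 0.00223 at the lowest of its alternatives. The injury median of 0.19 was 0.11 without homozygous replicate 4 and -0.0008 on log2 TPM. Lists of excitatory (camera adjusted p = 0.767) and inhibitory interneurons (0.723), of sensory ganglion neurons (0.767) and of ependymal cells (0.896) were not called.

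Cholesterol synthesis genes were lower as a group. Of 20 genes 6 fell, and 16 adjusted over the list alone, and 0 had a positive log2 fold change. Hmgcs1, which makes the substrate of the rate-limiting enzyme, fell from 382 ± 31.1 to 229 ± 43.0 CPM (log2 fold change -0.73, SE 0.12, edgeR adjusted p = 0.0345). Mvd, an enzyme of the mevalonate steps, fell from 21.9 ± 3.41 to 12.9 ± 1.84 CPM and Hsd17b7, an enzyme of the later sterol steps, from 28.6 ± 1.98 to 20.9 ± 1.63 CPM. The call was lost by Hsd17b7 in 7, Mvd in 6 and Hmgcs1 in 5 of the 7 fits with 1 library left out. The list median was -0.46 (camera adjusted p = 1.11e-18; adjusted p = 0.37 with an estimated correlation). In the library labelled homozygous replicate 1 Hmgcs1 was at 275 CPM, and the list mean was 5.65 log2-CPM, below the lowest heterozygous mean of 5.74. Of 16 lipid peroxidation and antioxidant genes, Fth1, the ferritin heavy chain gene, rose from 1874 ± 119.8 to 2777 ± 410.5 CPM; adjusted over the list alone 4 rose and 2 fell, and the list was not called (camera adjusted p = 0.407). Of lipid droplet genes, also not called (0.767), 3 were higher and 2 lower adjusted over the list alone, and the droplet coat gene Plin4 was at 12.2 ± 7.83 and 63.7 ± 30.0 CPM and did not pass. Medians and means of these last 2 lists differed in sign. The lists of COPI, ARF and Golgi genes (0.707) and of endoplasmic reticulum stress (0.912) were not called; in the latter Ddit4, an inhibitor of mTOR signalling, rose with a log2 fold change of 0.74 (SE 0.13, edgeR adjusted p = 0.0368). Ddit4 and Fth1 each lost the call in 5 of the 7 fits with 1 library left out.

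The endothelial list was lower and that of mitochondrially encoded genes higher. Slco1c1, a thyroid hormone transporter of brain capillaries, fell from 64.3 ± 9.51 to 34.9 ± 2.97 CPM (log2 fold change -0.87, SE 0.12, edgeR adjusted p = 0.0173), the only one of 10 endothelial genes to pass, while 6 fell adjusted over the list alone (camera adjusted p = 8.28e-09; adjusted p = 0.37 with an estimated correlation). The endothelial median of -0.45 was -0.74 without homozygous replicate 4. Genes of mural cells had a median of -0.17, which was -0.060 without heterozygous replicate 3, -0.074 without homozygous replicate 2 and -0.40 without homozygous replicate 4, with none of 9 past the test and 2 lower adjusted over the list alone (camera adjusted p = 0.0201; adjusted p = 0.651 with an estimated correlation). The mural cell call was lost without heterozygous replicate 3 (adjusted p = 0.117) or homozygous replicate 3 (0.105) and with limma-voom (0.0596), limma on log2 TPM (0.168) or Xist as a covariate (0.109), against 0.000346 at the lowest of its alternatives. Of 10 mitochondrially encoded genes 5 rose, and 10 adjusted over the list alone. Among them mt-Cytb rose from 6806 ± 609 to 10528 ± 977 CPM and mt-Nd2 from 3375 ± 276 to 5177 ± 624 CPM (camera adjusted p = 1.36e-15; adjusted p = 0.37 with an estimated correlation). The call was lost by mt-Cytb and mt-Nd2 in 5 and Slco1c1 in 3 of the 7 fits with 1 library left out. Homozygous replicate 3, with the highest mean of this list, also had 2.44% ribosomal bases, against at most 0.340% in the other 7. Erythroid genes, 5 tested with 0 past edgeR's test over all genes and adjusted over the list alone, were higher as a list (camera adjusted p = 0.037; adjusted p = 0.651 with an estimated correlation). The erythroid call was lost without heterozygous replicate 1 (adjusted p = 0.157), heterozygous replicate 2 (0.0778), heterozygous replicate 4 (0.0983) or homozygous replicate 4 (0.453) and with Xist as a covariate (0.074), against 4.14e-05 at the lowest of its alternatives. Genes of oligodendrocyte precursors, 13 tested with likewise 0 past edgeR's test, were lower as a list (camera adjusted p = 0.037; adjusted p = 0.651 with an estimated correlation). The precursor call was lost without heterozygous replicate 3 (adjusted p = 0.0868), heterozygous replicate 4 (0.198) or homozygous replicate 3 (0.341) and with limma on log2 TPM (0.258), against 1.86e-05 at the lowest of its alternatives.

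Among the genes with the largest changes or smallest p outside the groups above, Sult1a1, a sulfotransferase gene, rose from 6.75 ± 1.66 to 22.9 ± 5.73 CPM, Glp2r, a peptide hormone receptor gene, from 3.36 ± 0.671 to 9.95 ± 3.29 CPM, Phyhd1 from 8.17 ± 1.39 to 23.9 ± 6.96 CPM, Lrg1 from 0.595 ± 0.127 to 1.88 ± 0.206 CPM and Rtp1 from 0.589 ± 0.170 to 3.67 ± 2.17 CPM. The metabotropic glutamate receptor gene Grm3 fell from 43.5 ± 2.82 to 26.6 ± 0.969 CPM (log2 fold change -0.70, SE 0.07, edgeR adjusted p = 0.00732), the growth factor receptor gene Fgfr2 from 57.9 ± 5.87 to 34.3 ± 2.67 CPM, Apln, which encodes the peptide apelin, from 37.6 ± 3.87 to 19.8 ± 3.26 CPM, Psd2 from 68.5 ± 5.02 to 43.1 ± 4.43 CPM, Mfap3l from 61.4 ± 3.54 to 40.7 ± 2.13 CPM and Hivep1 from 95.0 ± 4.76 to 65.0 ± 3.21 CPM. With 1 library left out, the call was lost by Rtp1 in 5, Glp2r and Lrg1 in 4, Fgfr2, Apln and Psd2 in 2 and Sult1a1, Grm3, Mfap3l and Hivep1 in 1 of the 7 fits.

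**Figure D2:**
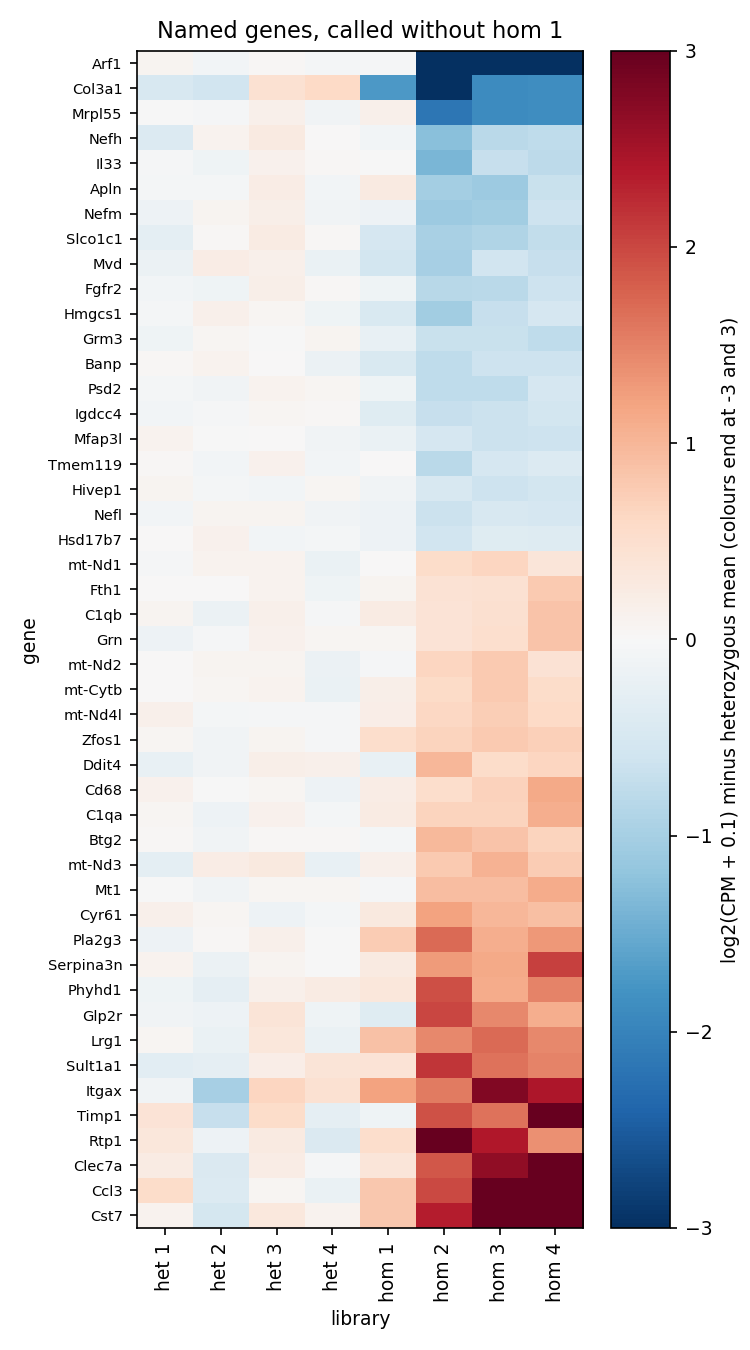
Lines are genes named by rule that passed without the library labelled homozygous replicate 1, columns are libraries, and the colour gives log2(CPM + 0.1) minus the heterozygous mean, with colours ending at -3 and 3. In hom 1 Arf1 (308 CPM) and Mrpl55 (14.5 CPM) stood at the heterozygous level and Col3a1 (2.33 CPM) lay with the other homozygous libraries.

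Over all lists, 7 were called higher and 10 lower of 39 tested with 8 libraries, and 9 and 10 without the library labelled homozygous replicate 1. With an estimated correlation none was called in either fit, with a smallest adjusted p of 0.397 and 0.37, and fry called 1 and 1. The 10 lower lists of the 8 libraries became 6 without heterozygous replicate 3, and the 9 higher lists of the 7 libraries became 5 without homozygous replicate 4 and 14 without homozygous replicate 2. Calls made with 8 libraries were lost as follows. The motor neuron list lost it without heterozygous replicate 3 (adjusted p = 0.057) and with limma on log2 TPM (0.237), against 9.86e-09 at the lowest of its alternatives. Resting microglia lost it without heterozygous replicate 3 (adjusted p = 0.117) and with limma on log2 TPM (0.0648), against 3.95e-05 at the lowest of its alternatives. MHC class II lost it with limma on log2 TPM (adjusted p = 0.0857), against 0.000129 at the lowest of its alternatives. The pan-neuronal list lost it without heterozygous replicate 1 (adjusted p = 0.0767), heterozygous replicate 2 (0.203), heterozygous replicate 3 (0.057), homozygous replicate 2 (0.0613) or homozygous replicate 4 (0.182) and with limma-voom (0.0653) or Xist as a covariate (0.106), against 0.000949 at the lowest of its alternatives. The lysosomal list lost it without heterozygous replicate 1 (adjusted p = 0.0769), heterozygous replicate 2 (0.107) or homozygous replicate 4 (0.293) and with limma-voom (0.0728), limma on log2 TPM (0.139) or Xist as a covariate (0.0727), against 0.00212 at the lowest of its alternatives. The complement list lost it with limma-voom (adjusted p = 0.0501), against 2.2e-05 at the lowest of its alternatives. Skeletal muscle genes were not called (camera adjusted p = 0.283 and 0.154); Ckm, the muscle creatine kinase gene, was at 79.9 CPM in heterozygous replicate 1, 7.29 CPM in the library labelled homozygous replicate 1 and at most 1.85 CPM in the other 6. Xist was at 388 CPM in heterozygous replicate 4 and 411 CPM in homozygous replicate 4, with the Y-linked gene Ddx3y at 2.63 and 3.91 CPM. In the other 6 libraries Ddx3y was at 39.9 to 50.7 CPM and Xist at 0 to 44.4 CPM.

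**Figure D3:**
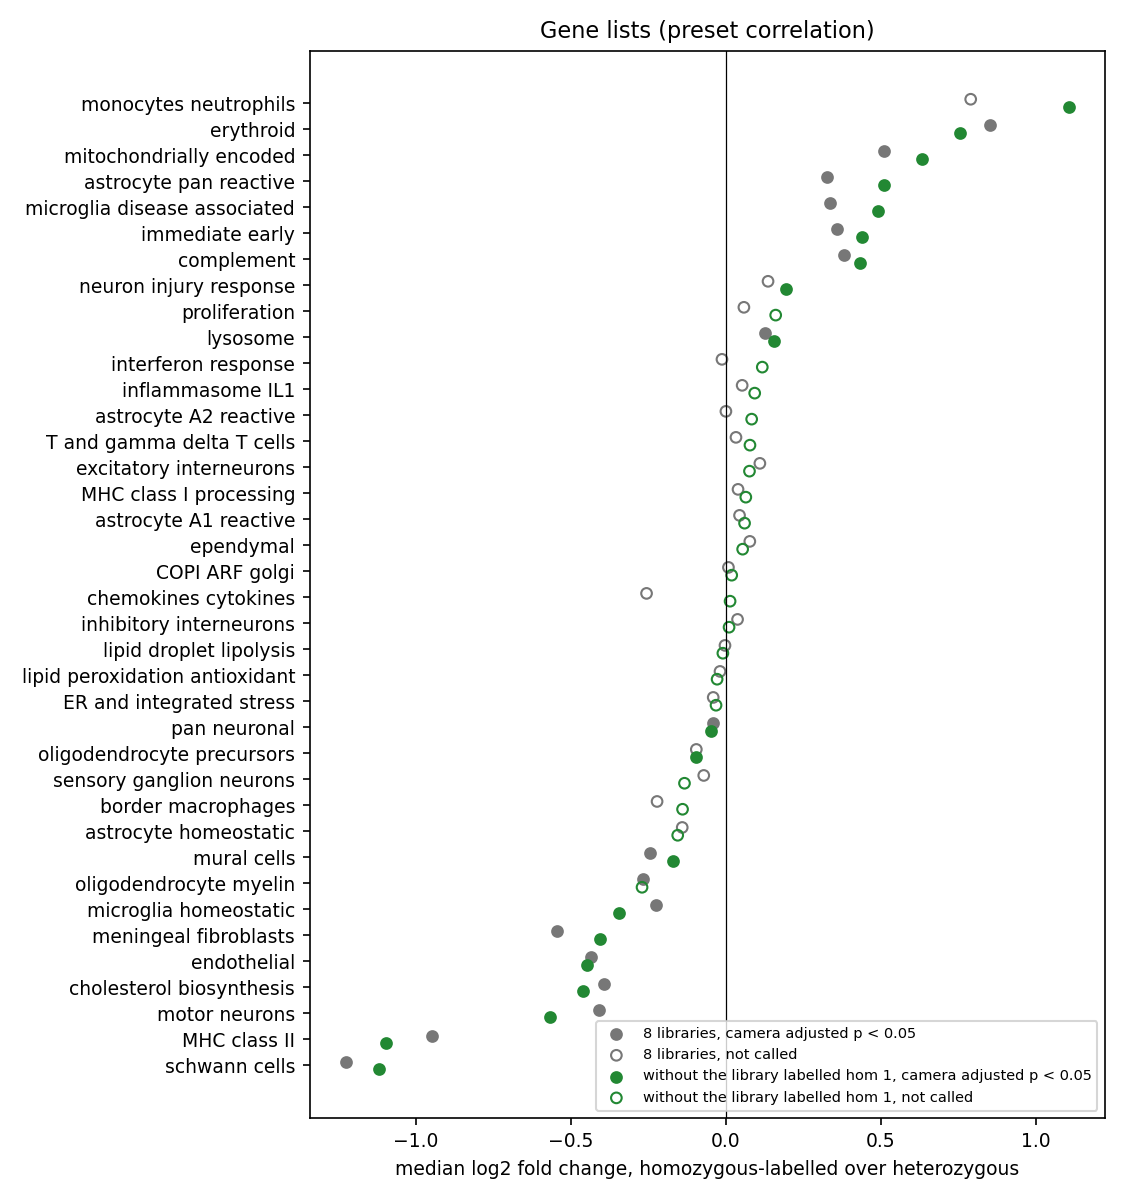
Points give the median log2 fold change of the tested genes of each list, for 8 libraries (grey) and without the library labelled homozygous replicate 1 (green), and filled points passed camera with the preset correlation. The skeletal muscle list (medians -2.42 and -3.44) is left out; cholesterol synthesis lay at -0.39 and -0.46, and mitochondrially encoded genes at 0.51 and 0.63.

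**Figure D4:**
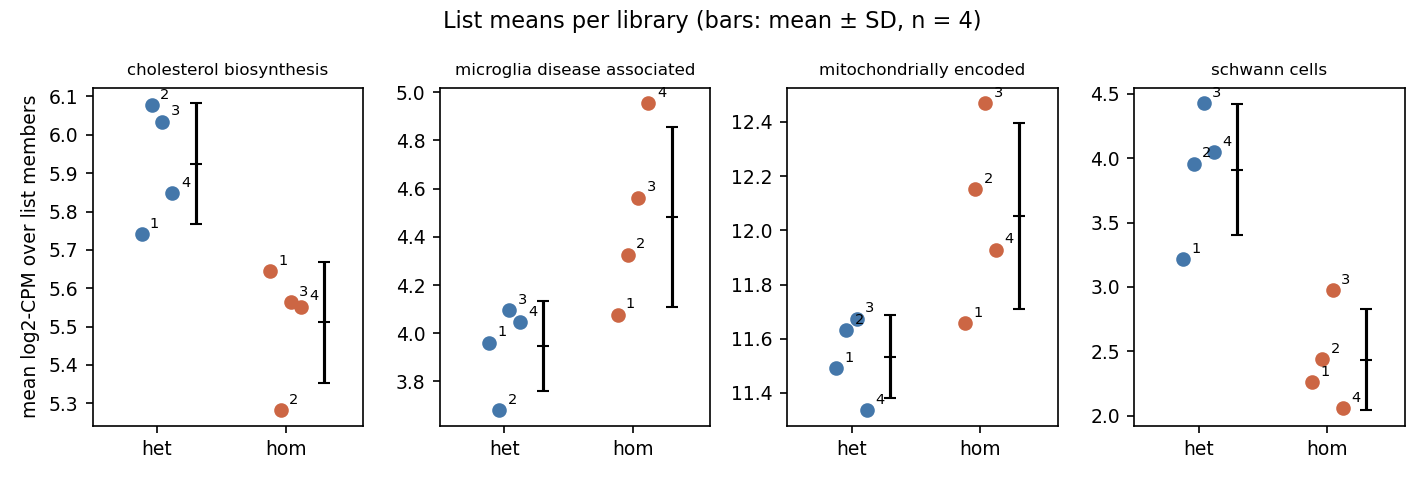
Points give the mean log2-CPM of 4 lists in each library, and bars the mean and SD of each group (n = 4). The Schwann cell mean lay between 3.21 and 4.43 in the heterozygous libraries and between 2.06 and 2.98 in those labelled homozygous, and that of disease-associated microglia was 4.08 in hom 1, within the heterozygous range.

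**Figure D5:**
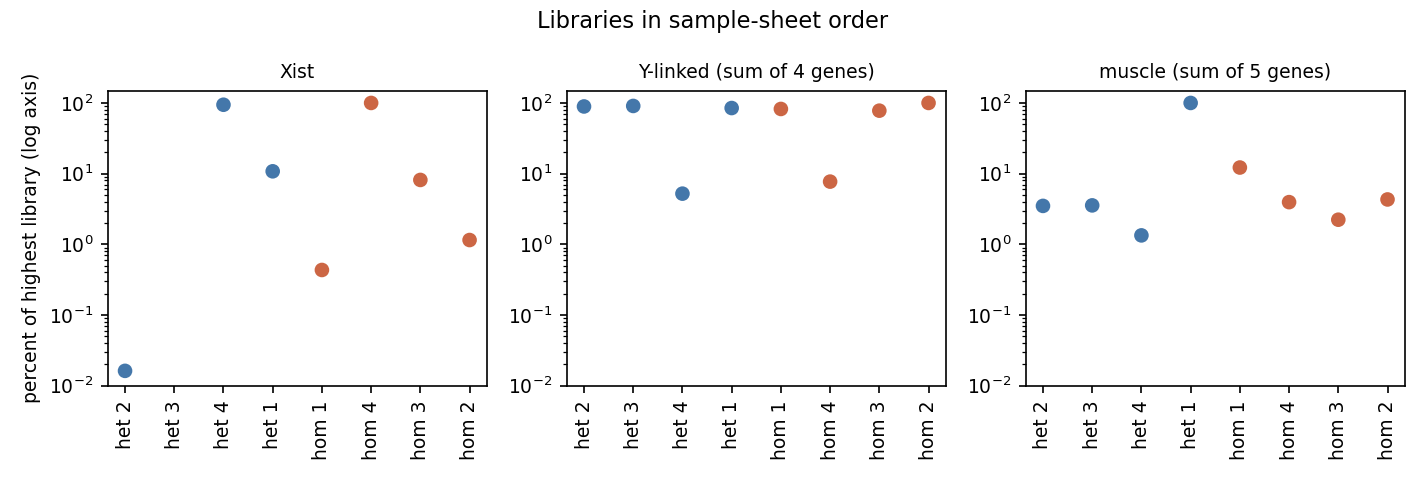
Points give Xist, the sum of 4 Y-linked genes and the sum of 5 muscle genes in each library as a percent of the highest library, on a log axis, with libraries in the order of their sample-sheet numbers. Xist in het 1 was at 10.8% and muscle in hom 1 at 12.2% of the highest library, and Xist in het 3 was at 0 and has no point.

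The authors' deposited table of their own comparison lists 75 higher and 110 lower genes. Its limits differ from the 0.05 used here: it runs to a false discovery rate of 0.0936, with 170 genes under 0.05, and holds no absolute log2 fold change under 1. Per the authors' deposited table, Arf1 had a log2 fold change of -3.50, Mrpl55 of -2.06 and Dhh of -3.84. The tables deposited beside it hold 6 libraries, without heterozygous replicate 1 and the library labelled homozygous replicate 1. Of the 173 listed genes tested with 8 libraries, 172 had the sign of the authors' deposited table, 0 were called by edgeR, and 144 had that sign at an unadjusted p under 0.05. With the library labelled homozygous replicate 1 left out, 40 of 174 were called with that sign, and with the 6 libraries 59 of 174. The 6 libraries gave 72 higher and 160 lower genes, of which 144 were among the 202 called without the library labelled homozygous replicate 1. These fits share 6 libraries, so their overlap is not independent evidence. The sign shared with the authors' deposited table is not independent evidence either. Its genes were listed for large changes, and the tables beside it hold 6 of these 8 libraries.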

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

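All tests in this part were chosen after the result was seen, except the position test of the library labelled homozygous replicate 1. One library stood apart from the other 3 of its group in 13 of 210 groups of values. Chance gives about 1 in 20 where groups are picked without regard to their values. Many of the genes checked were named for a small p without the library labelled homozygous replicate 1, which favours tight groups, so that rate need not hold. The numbers that follow are the gap to the nearest library over the range of the group. In the library labelled homozygous replicate 1 it was 0.840 for Mt1 and 0.871 for Mrpl55. It was 0.885 for Col3a1 in homozygous replicate 2, 0.868 for Btg2 in heterozygous replicate 2, and 0.834 for mt-Nd4l and 0.896 for the mean of the nerve injury list in heterozygous replicate 1. In heterozygous replicate 3 it was 0.872 for Apln, 0.917 for Glp2r, 0.892 for the mean of the inflammasome list and 0.872 for that of the chemokine list. Homozygous replicate 3 stood apart in mapped reads (0.987, 92.36%) and ribosomal bases (0.933, 2.44%), and homozygous replicate 4 in RNA integrity number (1, with 8 against 9). The other 3 of its group shared the same integrity number, so any differing value gives 1.

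The first pattern is Arf1 at the heterozygous level in the library labelled homozygous replicate 1. Arf1 was not flagged there by the gap used above, and the pattern was taken up because the level goes against the label. A swap with a heterozygous library is argued against, since the lowest heterozygous Arf1 level was 7.47 times the highest of the other homozygous libraries. Carry-over from the library with the preceding sample-sheet number is argued against too, since it would need 84.0% of that library. An animal without the ablation, or a wrong label, may explain it and stays open: over the 202 genes called without this library its median position was 0.318 (0 the heterozygous mean, 1 that of the other homozygous libraries), between the bounds of 0.25 and 0.75 set before the result was seen. Over 200 genes chosen without the library concerned, heterozygous libraries lay at 0.0831 to 0.249 and homozygous replicates 2, 3 and 4 at 0.916, 0.880 and 0.474. The labels give no group without a deletion, so the Arf1 level of an animal without the ablation is not known. An absent ablation and a wrong label were not told apart.

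The second pattern is the low level of Schwann cell genes in the 4 libraries labelled homozygous. Loss of Arf1 RNA as the whole cause stays open: the library labelled homozygous replicate 1 kept Arf1 and had a Schwann cell list mean -0.95 log2-CPM from the lowest heterozygous library, beyond the heterozygous SD of 0.51, but this is 1 library, whose own label stays open. Less nerve root and meningeal tissue in the homozygous-labelled samples could also lower these genes and stays open, with the fibroblast list mean of 2 of these libraries within the heterozygous range and of the other 2 below it. The first bound for this test, under which those 2 libraries would have counted against less root and meningeal tissue, was changed after the values were seen, because they lay above the lowest heterozygous library by less than the heterozygous SD of 0.48. An effect of the genotype on Schwann cells was not tested.

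The third pattern is Xist in libraries with Y-linked transcripts, Y-linked transcripts in libraries with high Xist, and muscle transcripts. Index exchange across the whole lane is argued against by the lowest Xist level among the 6 libraries with Y-linked transcripts, 0 CPM in heterozygous replicate 3, and by 0.0667 CPM in heterozygous replicate 2, beside 44.4 CPM in heterozygous replicate 1 and 33.5 CPM in homozygous replicate 3. Carry-over from the library with the preceding sample-sheet number is a candidate explanation: 0.357% of the 40320 orders of the libraries gave as large a match between neighbours. The heterozygous libraries hold sheet numbers 52 to 55 and those labelled homozygous 56 to 59, so effects of genotype and of sheet order cannot be told apart. Arf1 was at 39.8 CPM in homozygous replicate 4 (number 57), after 308 CPM in the library labelled homozygous replicate 1 (number 56). Whether carry-over raised it was not tested. Muscle left on the cord of single animals stays open, and no biological explanation was tested.

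Other splits of the same libraries into groups of the same sizes were run as well. With 8 libraries the real split called 0 genes and the highest other 1; any split has at least 0, so the count of 35 of 35 decides nothing. Without the library labelled homozygous replicate 1 the real split, 1 of 35, called 202 genes and the highest other 0. No smaller share is possible with 35 splits. The set of libraries was chosen with the Arf1 level of the left-out library in view. For the number of genes in this set the splits argue against chance without excluding it. For the lists chance cannot be excluded: 17 with 8 libraries against 26 in the highest other split (14 of 35 had as many), and 19 without the library labelled homozygous replicate 1 against 28 (10 of 35). The 6 libraries make too few splits for a share under 0.05; the real split, 1 of 10, gave 232 genes and the highest other 0.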

How the results depend on the processing

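The 6 libraries and all alternatives within the 7 libraries were tests chosen after the result was seen. With 8 libraries the counts of 0 higher and 0 lower genes became 21 and 50 at an adjusted p of 0.1, 19 and 44 with no filter, 270 and 409 with DESeq2, 1 lower on log2 TPM, and 72 and 160 with the 6 libraries; with 1 library left out they ranged over 0 to 91 and 0 to 111. The log2 fold change of Arf1 passed at -3.43 with the 6 libraries and ranged from -3.46 to -1.34 with 1 library left out; DESeq2 gave it no adjusted p. The 7 higher lists became 0 with an estimated correlation, 1 with fry and 4 with limma-voom, over 5 to 9 with 1 library left out; the 10 lower lists became 0, 0 with fry and 5 on log2 TPM, over 6 to 11, the lowest without heterozygous replicate 3. Genes called with the sign of the authors' deposited table went from 0 to 144 at an unadjusted p, 40 without the library labelled homozygous replicate 1 and 59 with the 6 libraries. Without the library labelled homozygous replicate 1 the 91 higher and 111 lower genes became 367 and 467 at an adjusted p of 0.1, 27 and 15 at an absolute log2 fold change of at least 1, 157 and 287 with no filter, 431 and 650 with DESeq2, 69 lower with a fit that was not robust, 2095 lower on log2 TPM, where the median of all genes moved by -0.17, and 33 and 30 with Xist as a covariate; with 1 more library left out they ranged over 3 to 139 and 3 to 263. The 9 higher lists became 0 with an estimated correlation and 1 with fry, over 5 to 14, lowest without homozygous replicate 4 and highest without homozygous replicate 2; the 10 lower lists became 0, 0 with fry and 5 on log2 TPM, over 7 to 11. Among named genes signs turned for Arf paralogs only, and among called lists for the median of the lysosomal list (-0.053 with 8 and -0.066 with 7 libraries) and of the nerve injury list with 7 libraries, on log2 TPM. With 8 libraries Arf3, Arf4 and Arf5 were at -0.076, -0.025 and -0.026 on log2 TPM, and Arf6 at 0.0011 with at least 1 CPM in 4 libraries and over -0.030 to 0.033 with 1 library left out; without the library labelled homozygous replicate 1 they were at -0.11, -0.05, -0.012 and 0.00013, and over -0.050 to 0.048. Of the other comparisons of named genes without the library labelled homozygous replicate 1, 584 kept their side of the threshold, 197 lost the call and 1 gained one (Arf2 on log2 TPM), and of those of called lists 237 kept it and 28 lost it. With 8 libraries 215 comparisons of named genes kept their side and 47 gained a call, and 240 of called lists kept it and 32 lost it. The cause was not tested, apart from the shift on log2 TPM. Genes under 1 CPM rest on few counts, such as Nlrp3, and Cst7 and Ccl3 in the heterozygous libraries. Cst7 and Ccl3 still passed without the library labelled homozygous replicate 1. A limit set by depth was not tested.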

Other observations

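The genes Penk, Tac1 and Cd4 were chosen after their values were seen, were tested as no group and did not pass edgeR's test in either fit. Penk, which encodes enkephalin, was at 209 and 202 CPM in the library labelled homozygous replicate 1 and homozygous replicate 2, and at 51.3 and 79.7 CPM in homozygous replicates 3 and 4, against 67.2 ± 5.59 CPM in the heterozygous libraries (SD, n = 4). Tac1, which encodes substance P, was at 44.7, 41.7, 11.6 and 18.9 CPM in the same order, against 12.8 ± 1.86 CPM. Cd4, a gene of the T cell list also expressed by other cells, was at 8.31, 9.72, 0.721 and 0.846 CPM, against 1.47 ± 0.778 CPM.

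Ighm, the immunoglobulin heavy chain gene of a list with too few tested genes, fell from 35.6 ± 4.12 to 15.7 ± 5.05 CPM (SD, n = 4 and 3) without the library labelled homozygous replicate 1 (log2 fold change -1.17, SE 0.20, edgeR adjusted p = 0.0405), and was at 30.1 CPM in that library. Per the authors' deposited table the caudal genes Hoxc11 and Hoxc10 had log2 fold changes of -2.94 and -1.67. In the libraries these varied within groups: Hoxc11 was at 0.0533, 1.63, 2.47 and 0.867 CPM in heterozygous replicates 1 to 4 and at 0.918, 0.0370, 0.481 and 0.163 CPM in replicates 1 to 4 labelled homozygous.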
